A study of Mus musculus with 21 samples.

How the data were processed

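The data are gene-level RNA sequencing values of 21 mouse libraries, 7 each of MEFs, SKOM cells without vitamin C and SKOM cells with it. Per the labels' protocols, the fibroblasts came from ICR embryos, total RNA was extracted with Trizol and libraries were made with a TruSeq RNA kit. The submitters' processing notes name Bowtie, RSEM and the mouse build mm10, without versions or roles. The strand setting, the normalization and the gene filter are not given in the sources used here.

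The deposited values are of the unit score: whole numbers on a scale like read counts, which the authors had already normalized. The sorted values of the libraries within a table are nearly the same list, with the same median in the 7 libraries of each SKOM table, and the lists differ between the 3 tables, so each table was normalized by itself. The 5C library and the MEF Tet1CD library followed the shared list less closely, with 97.1% and 35.8% of ranks holding another value than in the control. In each library 10 genes (9 in MEF Tet1CD) share the highest value, which is 38803 in MEFs, 19681 without vitamin C and 28926 with it, so changes among the most abundant genes are limited by a ceiling. Every gene has a value of at least 32 in at least 2 libraries of its table. Such values carry no depth: totals run from 4476522 to 4478695 in the Vc- table and say nothing about reads, so no counting error or detection limit was computed, and a gene at 0 is described as listed at 0. The tables hold 11152, 10723 and 12021 genes, of which 10711 are in both SKOM tables and 10238 in all 3. All value columns were used. Gene identifiers were matched to GENCODE M21 (99.5% found), and 98.8% of those lay within the same gene of that annotation with a tolerance of 200 bp. Coordinates are those of mm10, counted from 1.

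Values were transformed as log2(value + 5), and genes with a mean of at least 10 over the libraries fitted were kept. Groups were taken from the sample titles. The main test was limma 3.58.1 (empirical Bayes with an intensity trend) in R 4.3.3, with Benjamini-Hochberg adjustment and an adjusted p under 0.05. The additive model over the 14 SKOM libraries had terms for vitamin C, Dnmt1, shDnmt1, Tet1CD and shp53 and 8 residual degrees of freedom. Differences of a construct's effect between media came from the same model with 4 interaction terms (4 residual degrees of freedom), and differences of the Tet1CD effect with the Dnmt1 constructs from a model with 6. Separate fits to each SKOM table had 2 residual degrees of freedom. The residual spread of all these fits holds any departure from additivity as well as noise between libraries.

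Tests between tables had been planned for vitamin C and for SKOM against MEF cells and were not run, because the tables were normalized separately. In their place, the log2 ratio of each pair of libraries with the same construct was centred on that pair's median, and genes with the same direction in every pair and a median of at least 2-fold were counted. Each MEF combination of constructs had 1 library, and MEF effects are given as ratios of 2 libraries over 9928 genes with a mean of at least 50, with no p-value. A list's median ratio was placed among 10000 random lists of the same size matched on mean expression. For shp53 in MEFs, both disjoint pairs had to reach a log2 ratio of 0.58.

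A set of 27 gene lists with 696 members was fixed, with the design, the alternatives and the rule for named genes, before the data were examined; 22 lists had at least 3 measured members in the additive model. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, under which no list kept an adjusted p under 0.05 in the comparisons of the main models, and 1 list, the immediate early genes for shp53, kept it in the added model with a Vc by Tet1CD term. Members were counted over all genes and adjusted over the list alone. The genes named are the targeted genes and the 4 factors, the 8 genes with the largest change in each direction past the threshold in each tested comparison (predicted genes and genes without a symbol left out, the 4 smallest p-values where none passed), up to 4 members per list described with the largest change past the threshold (otherwise up to 2 with the smallest p), and, for single libraries, the 5 largest ratios per direction with list members of at least 2-fold. A few are named outside this rule, as values chosen after they were seen: Ifit2 and Irf7 in the interferon group, Lyz2 and the MEF values of Wdr31, Rab3gap1, Slc38a6 and Glipr1.

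The model code was tested on simulated data with the real genes' means and 200 changed genes. For the Tet1CD term it recovered 73.1%, 97% and 98.5% of genes changed by 0.58, 1 and 2 on the log2 scale, with 5.79% of calls false. The shares were 73.1%, 95.5% and 100% for shDnmt1 (3.24% false), 73.1%, 92.5% and 100% for Dnmt1 (4.84% false), 49.3%, 76.1% and 100% for shp53 (3.23% false), and 38.8%, 88.1% and 100% for Vc by Tet1CD (6.79% false). For Tet1CD in the Vc+ table alone they were 59.7%, 91% and 98.5%, with 12.2% of calls false.

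Alternatives were limma without the trend, quantile normalization across the libraries, a scaling in the manner of TMM (upper-quartile scaling for single-library ratios), pseudocounts of 1 and 20, no filter, a mean of at least 50, each library left out in turn, the MEF libraries added to the model, each SKOM table alone, pairs of libraries as a block, at least 2-fold change, and fry for the lists. Alternatives for the interactions and for the fits to each table, a Vc by Tet1CD term in the additive model, and the MEF library labelled Dnmt1 as reference were added after the data had been seen. Other splits of the libraries within their tables were fitted for Tet1CD, shDnmt1, the libraries labelled Dnmt1 and these against shDnmt1. They were also fitted for Vc by Tet1CD, Vc by shDnmt1 and Tet1CD in each SKOM table, but not for the other counts, those of shp53 included. The way of counting splits for Vc by Tet1CD was changed after results had been seen: earlier draws had given a share under 5%, and recomputing the 3 ways gave 5 of 100, 5 of 100 and 5 of 98 splits, of which the last, each distinct model once, is used. The test of lower Dnmt1 as the cause of the Atp5f1 and Erp29 changes was also narrowed after its values had been seen, from all hairpin pairs to those of SKOM cells and to each gene by itself. Copies of a repeat in transcripts were searched with blastn 2.17.0 (identity of at least 80% over at least 100 bp). Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.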

Results

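RNA was profiled in mouse embryonic fibroblasts (MEFs) and in cells on the way from fibroblasts to induced pluripotent stem cells. The reprogramming cells, called SKOM cells here, had received retroviruses for Sox2, Klf4, Oct4 (gene Pou5f1) and Myc and were harvested at day 5, in medium without vitamin C (Vc-) or with it (Vc+). Each culture also carried retroviral constructs aimed at DNA methylation or at p53. Dnmt1 is the maintenance DNA methyltransferase, and shDnmt1 is a hairpin against it. Tet1CD carries sequence of Tet1, an enzyme that oxidises 5-methylcytosine (CD usually stands for the catalytic domain), and shp53 is a hairpin against the tumour suppressor gene Trp53. The 21 libraries came in 3 tables of 7, and each combination of constructs was sequenced once in each setting. The values are whole numbers that had been normalized within each table before deposit, so sequencing depth is unknown. The median gene had a value of 208 in the MEF control, 180 in every Vc- library and 226 in every Vc+ library. Because each combination had 1 library, the effect of a construct in SKOM cells was estimated from all libraries that carried it, in an additive model over the 14 SKOM libraries. The labels do not say that libraries came from separate cultures, so the p-values measure only the spread between these samples. Fold changes are on the log2(value + 5) scale, which understates the change of genes with low values, and are given with their standard errors (SE).

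The targeted genes were read first, as a check of the labels. Dnmt1 (ENSMUSG00000004099, mm10 chromosome 9, 20907206 to 20959888) had a value of 957 in the MEF control and 208 with shDnmt1. In SKOM cells the corresponding values were 984 and 527 without vitamin C, and 2346 and 1154 with it. The libraries labelled Dnmt1 lay close to those controls, with 975 in MEFs, 1001 in Vc- cells and 2381 in Vc+ cells. Those labelled Tet1CD and Dnmt1 had 778 without and 1224 with vitamin C, against 967 and 1080 with Tet1CD alone. They are called libraries labelled Dnmt1 because of these values. Trp53 (ENSMUSG00000059552, chromosome 11, 69580359 to 69591873) was 1008 in the MEF control, 157 with shp53 and 186 with shp53 and shDnmt1 together. In SKOM cells the p53 hairpin came only together with shDnmt1, and Trp53 was 453 against 873 in the Vc- control and 621 against 1194 in the Vc+ control. Tet1 (ENSMUSG00000047146, chromosome 10, 62804577 to 62899118) was 2632, 2140 and 2448 in the 3 Vc- libraries with Tet1CD and 3129, 2591 and 2503 in the 3 Vc+ libraries, against 16 and 54 in the controls. Transcripts of the construct and of the resident gene cannot be separated in these values, and Tet1 is not listed in the MEF table. The same holds for the reprogramming factors, whose values add the retroviral transcripts to the resident ones. Myc stood at the highest value of the Vc- table, 19681, in the Vc- control, where 10 genes shared that value.

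**Figure D1:**
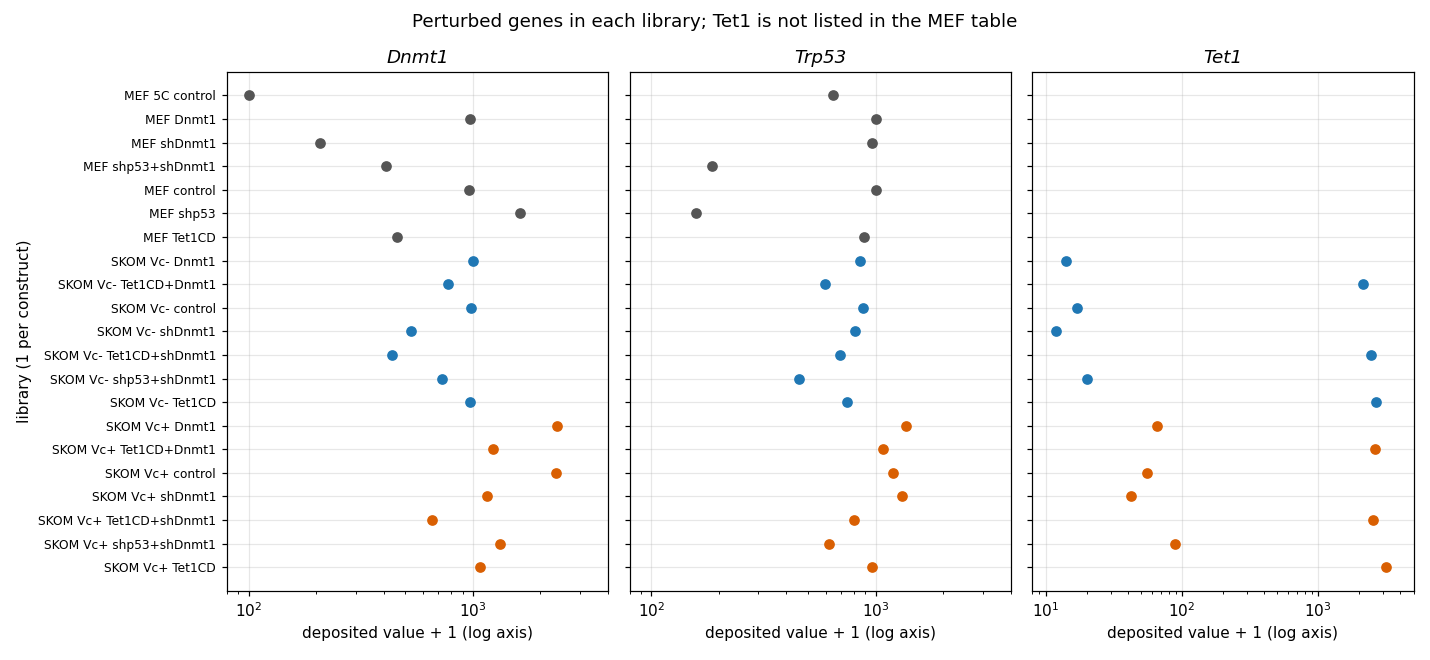
Values of Dnmt1, Trp53 and Tet1 plus 1, on a log axis, with 1 dot per library; grey dots are MEFs, blue dots SKOM cells without vitamin C and orange dots SKOM cells with it. Dnmt1 was 208 in the MEF shDnmt1 library against 957 in its control, and the libraries labelled Dnmt1 lay near their controls.

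The effect of Tet1CD in SKOM cells was estimated from 6 libraries with it and 8 without. Of the measured list members, 19 of 20 interferon-stimulated and 27 of 36 mesenchymal genes rose, while 30 of 30 G2/M genes, 33 of 34 G1/S genes, 8 of 11 epithelial genes and the 4 reprogramming factors fell. The calls of these lists as groups were lost, with adjusted p = 0.431 to adjusted p = 0.493 with an estimated correlation. Of 10711 genes, 2170 rose and 2672 fell (limma, Benjamini-Hochberg adjusted), 163 and 73 of them by at least 2-fold. Esm1 (ENSMUSG00000042379, chromosome 13, 113209659 to 113218098), a secreted endothelial proteoglycan, rose by 2.99 ± 0.49 (adjusted p = 0.000851), with values of 14 to 31 in the 4 Vc- libraries without Tet1CD against 55 to 87 in the 3 with it, and of 36 to 60 against 1049 to 1333 in Vc+ cells. Glipr1 rose by 2.58 ± 0.34 (adjusted p = 0.000296) and Mst1, the macrophage-stimulating protein, by 2.11 ± 0.20 (adjusted p = 7.79e-05). Rab3gap1 (2.47 ± 0.71) and Slc38a6 (2.17 ± 0.62) also rose, and both stood at the highest value of the Vc+ table, 28926, in Vc+ libraries with Tet1CD. Their response was larger with vitamin C by 4.66 and 4.06, so these rises rest mostly on the Vc+ libraries. Wdr31 (2.82 ± 0.90, adjusted p = 0.0239) rose in the 14 libraries together but had a change of -0.19 in the Vc- table alone. Clec4d, a lectin receptor of myeloid cells, rose (2.55 ± 0.50) with values no higher than 53. Among the genes that fell were Msc (-1.97 ± 0.27, adjusted p = 0.000342), which encodes the transcription factor musculin, Prr18 (-1.98 ± 0.30) and Csn1s1 (-1.72 ± 0.43), a milk casein. The cadherin gene Cdh7 (ENSMUSG00000026312, chromosome 1, 109982431 to 109995955) also fell, being listed at 0 in the 3 Vc+ libraries with Tet1CD against 84 to 90 in the other 4. Olfm3, Cntnap5a, Fut9 and Stxbp5l fell as well, each listed at 0 in at least 1 library with Tet1CD.

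All 30 measured genes of G2/M and mitosis fell (median log2 fold change -0.77; 30 adjusted over the list alone), among them the spindle checkpoint kinase Bub1b (-0.96 ± 0.14), the centromeric histone Cenpa (-0.93 ± 0.16), the mitotic motor Kif11 (-0.92 ± 0.12) and Birc5 (-0.92 ± 0.11). The limma camera test with the preset correlation called this list (adjusted p = 1.4e-13), with adjusted p = 0.431 with an estimated correlation. Of 34 genes of G1/S and replication 33 fell (median -0.67; 33 adjusted over the list alone), such as the replication initiation factor Mcm10 (-0.88 ± 0.14), the cyclin Ccna2 (-0.83 ± 0.12), the thymidine kinase Tk1 (-0.81 ± 0.11) and the helicase subunit Mcm3 (-0.79 ± 0.10). The list had adjusted p = 0.431 with an estimated correlation. Interferon-stimulated genes moved the other way. Of 20 measured, 19 rose (median 1.17; 19 adjusted over the list alone), including Rtp4 (1.86 ± 0.28), Oasl2 (1.82 ± 0.22), Xaf1 (1.75 ± 0.11, adjusted p = 5.77e-06) and the nucleic acid sensor Zbp1 (1.71 ± 0.20), while Ifit2 had a change of 0.29 ± 0.15 that did not pass the test. Here adjusted p = 0.431 with an estimated correlation as well. Irf7 (1.65 ± 0.23), a transcription factor of the response, was among the 19. Reads of near-identical family members such as the Oas genes could have been split between copies.

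Fibroblast and matrix genes rose with Tet1CD in the model over both media: 27 of 36 measured mesenchymal genes passed the test upward and none downward (28 adjusted over the list alone, median 0.50). Part of this list responded more upward with vitamin C, as given with the interaction below. Counts in the Vc- table alone are not given here for this list or for the epithelial list. Thrombospondin Thbs1 rose by 1.16 ± 0.16, collagen Col5a2 by 1.11 ± 0.22, the collagen crosslinking enzyme Lox by 0.99 ± 0.20 and N-cadherin (Cdh2) by 0.88 ± 0.18; for the list adjusted p = 0.431 with an estimated correlation. Epithelial genes fell in 8 of 11 cases, and 1 rose (8 and 1 adjusted over the list alone). Claudin 3 (Cldn3, -1.11 ± 0.29), E-cadherin (Cdh1, -1.06 ± 0.16), Epcam (-1.01 ± 0.27) and Cd24a (-0.69 ± 0.12) fell, whereas the desmosome gene Dsp rose by 0.28 ± 0.09 (list adjusted p = 0.493 with an estimated correlation). Senescence and secretory genes rose in 8 of 15 cases and fell in 1 (9 and 1 adjusted over the list alone), with Igfbp7 at 1.18 ± 0.17, the chemokine Ccl2 at 1.07 ± 0.26, Csf1 at 1.04 ± 0.14, the CDK inhibitor Cdkn2b at 1.03 ± 0.17 and the lamin gene Lmnb1 at -0.90 ± 0.15. This list had adjusted p = 0.431 with an estimated correlation. Of 12 immediate early genes 6 rose (6 adjusted over the list alone; adjusted p = 0.539 with an estimated correlation), the phosphatase Dusp1 by 0.91 ± 0.19. All 4 reprogramming factors fell, with changes of -1.15 ± 0.10 for Myc, -0.61 ± 0.18 for Klf4, -0.46 ± 0.13 for Pou5f1 and -0.45 ± 0.11 for Sox2 (4 adjusted over the list alone; adjusted p = 0.431 with an estimated correlation). In the Vc- table alone only Myc of the 4 passed (-1.07, from the ceiling of 19681), and the changes were -0.04 for Klf4, -0.17 for Pou5f1 and -0.14 for Sox2 (limma adjusted p = 0.814, 0.454 and 0.235). In the Vc+ table alone all 4 passed, with -1.18 for Klf4, -0.75 for Pou5f1, -0.76 for Sox2 and -1.23 for Myc. All 3 measured macrophage markers rose beside these groups: Ptprc and Laptm5 by 1.90 ± 0.42 and 1.90 ± 0.31, and Cd68 by 1.64 ± 0.32 (3 adjusted over the list alone; adjusted p = 0.431 with an estimated correlation). Of 8 measured pluripotency genes 2 rose and 4 fell (2 and 5 adjusted over the list alone), with alkaline phosphatase Alpl at -1.53 ± 0.35 and Lin28b at -0.51 ± 0.16.

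**Figure D2:**
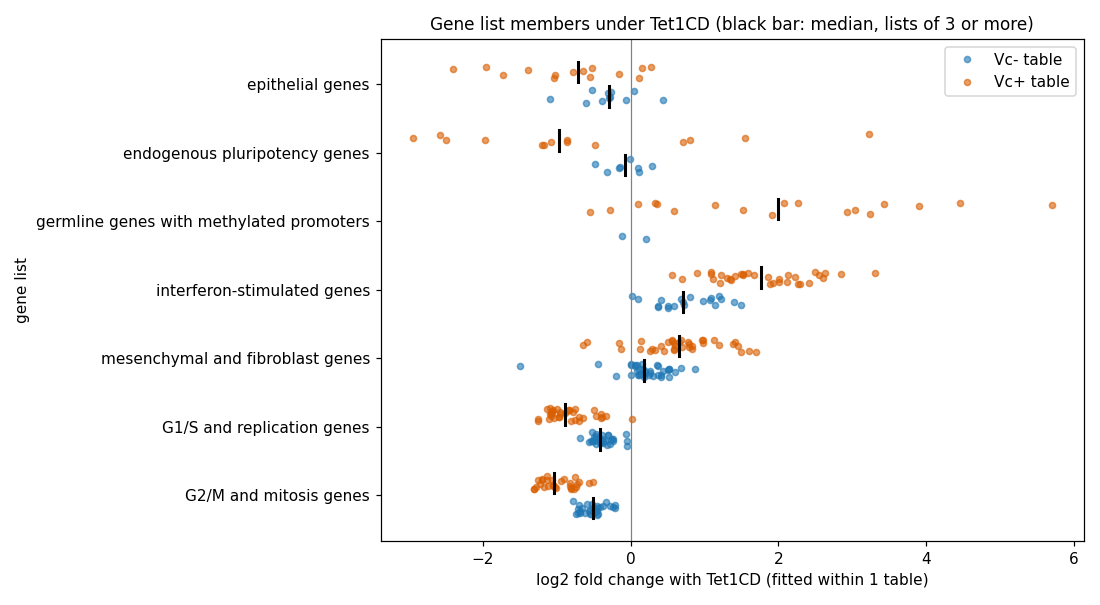
Log2 fold change with Tet1CD of each measured member of 7 gene lists, from separate fits to the Vc- table (blue) and the Vc+ table (orange); a black bar marks the median of a list with at least 3 members. Interferon members lie above 0 and G2/M members below 0 in both media, with medians of 0.71 and -0.51 without vitamin C and of 1.76 and -1.04 with it. More interferon members are listed with vitamin C, so their medians are not of the same genes.

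Tet1CD acted in both media when each table was fitted alone. Without vitamin C, the citrate carrier Slc13a5 (2.33 ± 0.18), the growth factor Hgf (1.91 ± 0.33), the quinone reductase Nqo1 (1.76 ± 0.27), Ddx60 (1.71), Glipr1 (1.55 ± 0.14) and Mst1 (1.54 ± 0.15) rose, as did Cdh19, and the orphan receptor Gpr50 (-1.23 ± 0.08), Msc (-1.17), Prr18 (-1.23), Tslp (-1.30) and Vat1l (-1.11) fell. In all, 777 genes rose and 791 fell of 10722, and 204 and 100 in limma without the intensity trend. Of the G2/M list 24 of 30 fell (29 adjusted over the list alone; adjusted p = 0.619 with an estimated correlation), of the G1/S list 21 of 34 (28 adjusted over the list alone; adjusted p = 0.619 with an estimated correlation), and 13 of 20 interferon-stimulated genes rose (15 adjusted over the list alone; adjusted p = 0.593 with an estimated correlation). These counts changed widely when single libraries were left out. Such fits can have fewer residual degrees of freedom than the 2 of the full fit, so a loss of calls can also be a loss of power. Without the Vc- library labelled Dnmt1, 3 genes rose and 2 fell, with 3 and 2 also without the Vc- library labelled Tet1CD and Dnmt1, 54 and 19 without the Vc- shDnmt1 library, and 37 and 18 without the Vc- library with Tet1CD and shDnmt1. The number that fell was 1195 without the Vc- control and 1202 without the Vc- Tet1CD library.

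With vitamin C, 10 of 18 measured germline genes, a class normally silenced by promoter methylation, rose with Tet1CD and none fell (12 adjusted over the list alone; median 2.00; adjusted p = 0.277 with an estimated correlation). A gene is listed only with a value of at least 32 in at least 2 libraries, so members near 0 without Tet1CD are listed because of their values with it, and the share and median partly follow from that filter. The germ cell RNA-binding protein gene Dazl (ENSMUSG00000010592, chromosome 17, 50279394 to 50293599) had values of 1, 1, 2 and 2 in the 4 Vc+ libraries without Tet1CD and of 222, 447 and 337 in the 3 with it (5.70 ± 0.24, adjusted p = 0.000156). Tex19.1 (ENSMUSG00000039329, chromosome 11, 121146143 to 121148319) went from 0 to 10 up to 90, 140 and 129 (4.45 ± 0.28). Piwil2, which works in the piRNA pathway, rose by 3.43 ± 0.19, Rhox5 by 3.24 ± 0.32, Taf7l by 3.04 ± 0.43 and Asz1 by 2.93 ± 0.40. Tuba3b, listed at 0 or 1 without Tet1CD, had 53 to 99 with it. Outside the list, Wdr31 (5.83 ± 0.16), Rab3gap1 (4.80 ± 0.21) and Cfap70 (4.93 ± 0.30) rose, and Pet2, listed at 0 in the 4 libraries without Tet1CD, had 69 to 132 with it. Arhgap36 (-3.16 ± 0.14), Ndufa4l2 (-3.00) and Slitrk4 (-2.93) fell. The germline list had only Sycp1 and Tex15 listed in the Vc- table, where no test of the list was made.

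Pluripotency genes moved in both directions in Vc+ cells with Tet1CD. Of 14 measured, 10 fell and 4 rose (10 and 4 adjusted over the list alone; median -0.97; adjusted p = 0.425 with an estimated correlation). Nr0b1 (-2.95 ± 0.36), Alpl (-2.57 ± 0.14) and the threonine dehydrogenase gene Tdh (-2.50 ± 0.30) fell. Dppa2, listed at 0 in 3 of the libraries without Tet1CD, had 39 to 46 with it, and Gdf3 rose by 1.54 ± 0.23. All 34 measured interferon-stimulated genes rose (34 adjusted over the list alone, median 1.76, adjusted p = 0.277 with an estimated correlation), among them Oas3 (3.31 ± 0.16), Isg15 (2.84 ± 0.15), Rtp4 (2.63 ± 0.10) and Ifit1 (2.61 ± 0.17). Only 20 genes of this list were measured in both media. Members near 0 without Tet1CD are listed because of their values with it, so the share and median can partly follow from that filter. Epithelial genes fell in 9 of 14 cases (10 adjusted over the list alone; adjusted p = 0.49 with an estimated correlation), with the splicing regulator Esrp1 at -2.41 ± 0.35 and Epcam at -1.73 ± 0.12. In all, 2483 genes rose and 2836 fell of 12021, 739 and 484 of them by at least 2-fold. Of the 1310 genes listed with vitamin C but not without it, 311 rose and 216 fell, counts that the same filter affects. The counts were 1186 and 1049 without the Vc+ library labelled Dnmt1, and 1146 and 1085 without the Vc+ library labelled Tet1CD and Dnmt1. In simulated data, 12.2% of the calls of this fit were false.

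Among 10710 genes tested in both media, 1221 passed the test in both, 1187 of them in the same direction and 34 in opposite directions, where independent lists would share 351 in the same direction. Of the 1221, 1086 changed more with vitamin C (median absolute log2 fold change 0.75 against 0.44). Across genes, which are not independent replicates, the Tet1CD changes in the Vc- and Vc+ tables had a Pearson correlation of 0.60.

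Whether the response to Tet1CD differed with vitamin C was tested as an interaction. With vitamin C 15 of 20 interferon-stimulated, 17 of 36 mesenchymal and 12 of 35 p53 target genes responded more upward, and 16 of 34 G1/S, 8 of 30 G2/M, 11 of 28 hypoxia-response and 6 of 22 cholesterol synthesis genes more downward. No list passed as a group, with adjusted p = 0.0991 to adjusted p = 0.335 with an estimated correlation for these. The difference was positive for 918 genes and negative for 887 of 10711 (limma), 241 and 133 of them by at least 2-fold. The 100 genes nearest in level to each of the 241 had a difference of 0.30 in the median. Wdr31 (ENSMUSG00000028391, chromosome 4, 62448653 to 62468888) led with 6.02 ± 0.21 (adjusted p = 2.11e-06): its values were 58, 70 and 86 in Vc- libraries with Tet1CD and 5366, 13554 and 8003 in Vc+ libraries with Tet1CD. Rab3gap1 (4.66 ± 0.25), D7Ertd715e (4.56 ± 0.23), Slc38a6 (4.06 ± 0.21), Cep112os2 (3.46 ± 0.34) and Kif24 (3.25 ± 0.27) followed. Baiap2l1, an actin-binding adaptor, differed by 3.77 ± 0.16 (adjusted p = 3.64e-06), with 51 to 68 in all 7 Vc- libraries, 73 to 91 in the Vc+ libraries without Tet1CD and 945 to 1142 with it. The cytokine gene Tslp differed by 3.28 ± 0.32 and had fallen with Tet1CD in the Vc- table. On the negative side stood Arhgap36 (-3.01 ± 0.37), the lactate exporter Slc16a3 (-2.96 ± 0.26), Frem2 (-2.30 ± 0.29), Bex4 (-2.18 ± 0.29), the planar polarity cadherin Celsr1 (-2.09 ± 0.19) and Alpl (-2.09 ± 0.34). Cdh7 and Fut9 also differed, with values of 0 in Vc+ libraries with Tet1CD.

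The interaction by group was as follows. Of 20 interferon-stimulated genes 15 responded more upward with vitamin C (18 adjusted over the list alone; median 0.88; adjusted p = 0.0991 with an estimated correlation), with Rtp4 at 1.54 ± 0.19 and Irf7 at 1.15. Of 36 mesenchymal genes 17 did (20, and 1 downward, adjusted over the list alone; adjusted p = 0.269 with an estimated correlation), with the collagen Col3a1 at 1.33 ± 0.23. Of 35 p53 target genes 12 did (18 adjusted over the list alone; adjusted p = 0.0991 with an estimated correlation), among them the apoptosis gene Pmaip1 (1.09 ± 0.12) and Plk2 (1.02). In the G1/S list 16 of 34 responded more downward (24 adjusted over the list alone; adjusted p = 0.222 with an estimated correlation), with E2f2 at -1.01 and Mcm10 at -0.75, and in the G2/M list 8 of 30 (11 adjusted over the list alone; adjusted p = 0.335 with an estimated correlation). Sox2 differed by -0.62 ± 0.12 and Klf4 by -1.14 ± 0.15, whose values were 4210 in the Vc- control and 4210 to 5059 with Tet1CD, but 7995 in the Vc+ control and 3886 to 4142 with Tet1CD. The macrophage markers Laptm5 and Cd68 differed by 1.85 ± 0.16 and 1.84. The counts fell to 486 and 324 without the Vc- control, 456 and 317 without the Vc- shDnmt1 library, 450 and 311 without the Vc- library with Tet1CD and shDnmt1, and 482 and 325 without the Vc- Tet1CD library. They were 488 and 369 without the Vc+ library labelled Dnmt1 and 483 and 380 without the Vc+ library labelled Tet1CD and Dnmt1, and the negative count was 577 without the Vc- library labelled Dnmt1 and 579 without the Vc- library labelled Tet1CD and Dnmt1.

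Few genes passed the test for the constructs aimed at Dnmt1 in SKOM cells. With shDnmt1, Atp5f1 (ENSMUSG00000000563, chromosome 3, 105942698 to 105960099), a subunit of the mitochondrial ATP synthase, fell by 0.97 ± 0.11 (adjusted p = 0.00939), and Erp29 (ENSMUSG00000029616, chromosome 5, 121428590 to 121452487), a chaperone of the endoplasmic reticulum, fell by 0.68 ± 0.08 (adjusted p = 0.0133). These were the only 2 genes of 10711 that passed the limma test (383 at an unadjusted p under 0.05). Dnmt1 had a change of -0.94 ± 0.15 that missed it over all genes (adjusted p = 0.153) and passed adjusted over the list alone (0.000772). In a model with a Vc by Tet1CD term, chosen after the data were seen, Dnmt1 passed over all genes (-0.94 ± 0.09, adjusted p = 0.00099), and 1 gene rose and 5 fell. There 775 genes had an unadjusted p under 0.05 in limma for shDnmt1. The median residual SD was 0.136 in that model against 0.164 in the additive one. The additive test was thus the less sensitive, and its few calls do not show a weak effect. No gene passed for the libraries labelled Dnmt1 (limma, 0 of 10711; 84 at an unadjusted p under 0.05), where the smallest p-values belonged to Zfp534 (1.86 ± 0.42), Gemin4 (0.52), Mthfsd (0.24) and Agtr2 (-1.84), each with adjusted p = 1. Between the libraries labelled Dnmt1 and those with shDnmt1, Atp5f1 (0.94 ± 0.11) and Erp29 (0.74 ± 0.08) were higher in the former (adjusted p = 0.00635 each), and no other gene passed (473 at an unadjusted p under 0.05). Neither call of the hairpin held without the Vc- control, the Vc- shDnmt1 library or the Vc+ library with Tet1CD and shDnmt1 (0 genes each). In the fit without the Vc- library with Tet1CD and shDnmt1 or without the Vc+ control, 1 gene passed. The contrast between the labels had 0 genes without either the Vc- library labelled Dnmt1, the Vc- library labelled Tet1CD and Dnmt1, the Vc- shDnmt1 library or the Vc+ library labelled Dnmt1.

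Gene groups moved little with these constructs. For the libraries labelled Dnmt1, camera with the preset correlation placed mesenchymal genes lower (median -0.12) and G2/M genes higher (median 0.08), with adjusted p = 0.901 for both with an estimated correlation, and 0 members of either passed singly (0 adjusted over the list alone). Between the libraries labelled Dnmt1 and those with shDnmt1, G2/M genes were placed higher (median 0.15; adjusted p = 0.907 with an estimated correlation) and G1/S genes too (median 0.10; adjusted p = 0.942 with an estimated correlation), again with 0 members passing in limma singly or adjusted over the list alone. The effect of Dnmt1 or shDnmt1 was tested for a difference with vitamin C and with Tet1CD, and limma called 0 genes in each case. The counts at an unadjusted p under 0.05 were 277 for Vc by Dnmt1, 408 for Vc by shDnmt1, 155 for Tet1CD by Dnmt1 and 305 for Tet1CD by shDnmt1. Across genes, the shDnmt1 changes in the 2 SKOM tables had a Pearson correlation of 0.08, those of the libraries labelled Dnmt1 -0.01.

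In SKOM cells the p53 hairpin was present in 1 library per medium, always with shDnmt1. A single gene fell in both media together: Palm2Akap2 (ENSMUSG00000089945, chromosome 4, 57568179 to 57896982), which overlaps Akap2, was listed at 0 in both libraries with the hairpin and at 61 to 152 in the other 12 (limma adjusted p = 3.44e-06). It was also listed at 0 in both MEF libraries with shp53 and in the 5C library described further on. No gene rose, and 1129 had an unadjusted p under 0.05. Cell cycle lists had medians above 0 and matrix genes a median below 0. No single member passed over all genes, and no list passed with an estimated correlation. The median log2 fold change was 0.38 for G2/M (0 adjusted over the list alone; adjusted p = 0.501 with an estimated correlation), 0.27 for G1/S (0 adjusted over the list alone; adjusted p = 0.501 with an estimated correlation) and -0.35 for mesenchymal genes (3 lower adjusted over the list alone; adjusted p = 0.501 with an estimated correlation). Immediate early genes had a median of -0.41, and 8 of 12 were lower adjusted over the list alone, among them Fos (-1.28 ± 0.23) and Egr1 (-0.77); adjusted p = 0.37 with an estimated correlation. The p53 target genes had a median of -0.23, with 3 lower adjusted over the list alone, Perp (-0.61) and Btg2 (-0.38) among them, and adjusted p = 0.501 with an estimated correlation. With a Vc by Tet1CD term in the model, 5 of the 12 immediate early genes fell over all genes (12 adjusted over the list alone; adjusted p = 0.0464 with an estimated correlation). With the MEF libraries added to the additive model 1217 genes rose and 1188 fell. In the model with the Vc by Tet1CD term 109 genes rose and 344 fell, such as the glutathione peroxidase Gpx3 (-1.56) and the inflammatory caspase Casp4 (-2.36) downward and Rcor2 (1.09), the histone chaperone Nasp (0.90) and the chaperonin Hspd1 (0.94) upward. The count of genes that fell was 5 without the Vc- library with shp53, 3 without the Vc+ library with shp53 or the Vc- library labelled Tet1CD and Dnmt1, and 2 without the Vc- Tet1CD or the Vc+ Tet1CD and shDnmt1 library.

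In the Vc- table alone, 4 genes rose and 9 fell with shp53. Since 1 library per table carried it, these tests and the one between media take their spread from the other libraries and assume that the lone library varies like them. The smooth muscle actin gene Acta2 (ENSMUSG00000035783, chromosome 19, 34241090 to 34255336) had 5063 with shp53 and the table's highest value, 19681, in the other 6 libraries, so its change of -1.96 ± 0.06 (adjusted p = 9.77e-05) is limited by that ceiling. Ces2g (-1.79), Gpx3 (-1.69), Prss23 (-0.90), the protease inhibitor Timp3 (-0.85), the elastic fibre gene Fbln5 (-0.83) and Prelp (-0.74) also fell. In the Vc+ table alone, Lum and Fap fell, both listed at 0 in the library with shp53 and at 30 or above in the other 6. The difference between media passed the test for 4 genes, all lower with vitamin C: Fap (ENSMUSG00000000392, chromosome 2, 62500943 to 62574075), Gabra3, Ddx5 and Hnrnpu (limma; 0 genes higher; 375 at an unadjusted p under 0.05). Fap and Gabra3 were listed at 0 in the Vc+ library with shp53 and at 67 and 48 in the Vc- one. This count was 11 without the Vc+ shDnmt1 library, with 17 genes higher. It was 0 without the Vc- shDnmt1 or the Vc- Tet1CD and shDnmt1 library, 1 without the Vc- library labelled Dnmt1 or the Vc- library labelled Tet1CD and Dnmt1, and 2 without the Vc- control, the Vc- Tet1CD, the Vc+ control, the Vc+ Tet1CD, the Vc+ library labelled Tet1CD and Dnmt1 or the Vc+ library labelled Dnmt1. Without the Vc+ Tet1CD and shDnmt1 library 1 gene was higher.

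In MEFs, where every combination of constructs had 1 library and no test was made, the p53 hairpin could be read in 2 pairs that share no library: shp53 over control, and shp53 with shDnmt1 over shDnmt1. Known p53 targets were lower and cell cycle genes higher in both. Of 35 measured p53 targets, 23 were lower in both pairs by a log2 ratio of at least 0.58. Trp53inp1, a p53 cofactor, went from 730 to 113 in the first pair and from 974 to 183 in the second, and the apoptosis effector Perp from 499 to 82 and from 343 to 82. The death receptor Fas went from 95 to 14 and from 109 to 24, Ccng1 from 19814 to 4125 and from 19814 to 5195, and the p53 ubiquitin ligase Mdm2 from 2279 to 802 and from 2017 to 826. In the G1/S list 28 of 34 genes and in the G2/M list 28 of 30 were higher in both pairs. The proliferation marker Mki67 went from 1590 to 4403 and from 857 to 2966, the topoisomerase Top2a from 1550 to 4006 and from 1087 to 3715, Ccna2 from 767 to 2156 and from 515 to 1787, and Mcm10 from 102 to 324 and from 97 to 248. Among 37 mesenchymal genes 8 were lower in both pairs and none higher, including Fbln2, which stood at the highest value of the MEF table, 38803, in the control. The TGF-beta receptor gene Tgfbr2 went from 1247 to 297 and from 807 to 259. Senescence and secretory genes were lower in both pairs in 7 of 20 cases and higher in 1, Lmnb1 (665 to 1423 and 438 to 1150). The 5 widest ratios of the first pair in each direction were those of Ptprv (318 to 21), Notch3 (285 to 23), Col10a1 (212 to 20), Iigp1 (37 to a listing at 0) and Tap1 (111 to 10) downward and of Htr2b (0 to 42), Prl2c2 (2 to 31), Tom1 (0 to 20), Tfap4 (36 to 159) and C1qa (1 to 16) upward. Htr2b (49), Prl2c2 (58), Tom1 (116), C1qa (30) and Iigp1 (3) also differed from this control in the library labelled Dnmt1, in the same directions. Their ratios cannot be credited to the p53 hairpin.

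Over all 9928 genes with a mean of at least 50, 587 were higher and 621 lower in both MEF pairs, where independent pairs would give 87.9 and 106, and 30 went opposite ways. At 2-fold, 246 were higher and 387 lower in the first pair and 309 and 272 in the second. The G2/M median was 1.11 in the first pair and 1.45 in the second, the G1/S median 0.92 and 1.18, each above all 10000 random lists of matched expression. The p53 target median was -1.03 and -0.88, below all of them. Interferon-stimulated genes went apart (median -0.97 and 0.45), as did macrophage markers (1.09 and -2.20), whose levels varied between the MEF libraries: Laptm5 was 6 in the control, 19 with shp53, 65 with shDnmt1 and 7 with both hairpins. Across genes, the 2 MEF pairs had a Pearson correlation of 0.62, and the shp53 changes of SKOM cells had correlations of 0.46 and 0.49 with them.

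**Figure D3:**
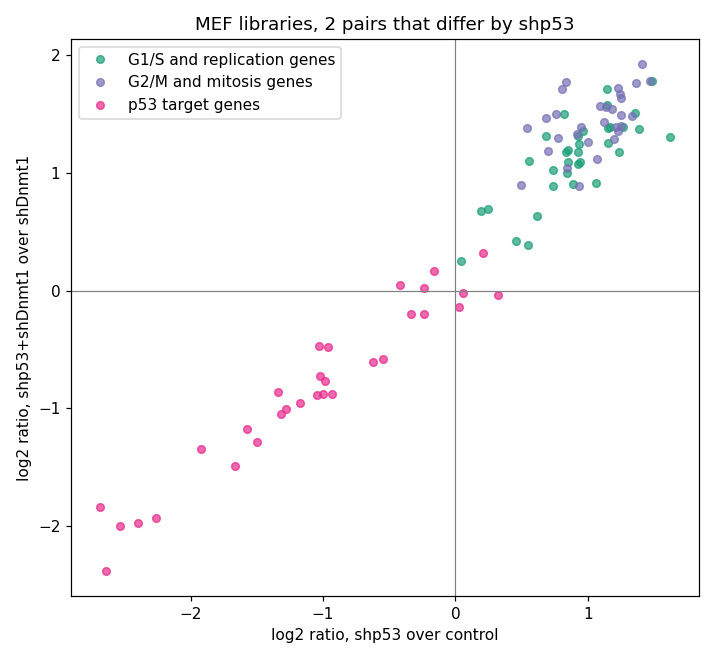
Log2 ratio of MEF shp53 over MEF control (x axis) against MEF shp53 with shDnmt1 over MEF shDnmt1 (y axis) for members of the G1/S, G2/M and p53 target lists, 1 dot per gene. The 28 of 34 G1/S and 28 of 30 G2/M genes higher in both pairs lie at the upper right, and the 23 of 35 p53 targets lower in both at the lower left.

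The other MEF constructs moved fewer genes at 2-fold. With shDnmt1, Dnmt1 itself (log2 ratio -2.18) and Atp5f1, from 2438 to 457, were among the 5 widest ratios downward, and Kcnh7 went from 71 to a listing at 0. Kcnh7 had 63 in the MEF library with shp53 and shDnmt1, so its listing at 0 was not shared by the other library with this hairpin. G2/M genes had a median log2 ratio of -0.58 and G1/S genes of -0.39. In all 39 genes were higher and 39 lower. The MEF library labelled Dnmt1 had 24 higher and 21 lower. Interferon-stimulated genes were lower in both libraries than in the control (median -0.83 for the library labelled Dnmt1 and -0.65 for shDnmt1), and macrophage markers were higher (median 2.19 and 1.94), with Laptm5 at 6 in the control, 59 and 65. Against the MEF library labelled Dnmt1 instead of the control, a reference chosen after the data were seen, the interferon median was 0.12 with shDnmt1, 0.09 with shp53 and 2.06 with Tet1CD. Adding shDnmt1 to shp53 left 80 genes higher and 41 lower than shp53 alone. In this other pair the interferon median was 0.56, with 8 of 25 genes at least 2-fold higher, and the macrophage median -1.64, with 5 of 6 at least 2-fold lower, both opposite in sign to shDnmt1 over the control. The G2/M median was -0.19 and the G1/S median -0.18. Across genes, the shDnmt1 ratios of the 2 pairs without shared libraries had a Pearson correlation of 0.15.

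Tet1CD in MEFs gave a higher interferon group and a lower cell cycle group. The interferon-stimulated genes had a median log2 ratio of 1.24 over the control, with 15 of 25 at least 2-fold higher, such as Usp18 (27 to 183). The G1/S and G2/M medians were -0.77 and -0.84, with 10 of 34 and 11 of 30 genes at least 2-fold lower, among them Mki67 (1590 to 667) and the checkpoint adaptor Clspn (323 to 110). Of 7 epithelial genes 3 were at least 2-fold higher (median 0.46), namely Krt18 (21 to 134), Krt7 (48 to 246) and the desmosome gene Dsp (110 to 366), whereas Krt19 went from 295 to 176. Of 34 imprinted genes 5 were at least 2-fold lower and 0 higher (median -0.19), with H19 from 9045 to 1439, Peg3 from 1788 to 673 and Grb10 from 6713 to 2796. Penk went from 507 to 66, Angptl7 from 243 to 43, Fbn2 from 504 to 116, and Xdh, which encodes xanthine dehydrogenase, from 14 to 227. In all 155 genes were at least 2-fold higher and 148 lower. Wdr31 (62 to 453), Rab3gap1 (575 to 3825), Slc38a6 (835 to 5204) and Glipr1 (550 to 3540) were higher here too. Macrophage markers had a median of 2.76 (Laptm5 from 6 to 89), and 5 of 6 were at least 2-fold higher. Against the MEF library labelled Dnmt1, a reference chosen after the data were seen, their median was 0.50, with 1 of 6 at least 2-fold higher. Across genes, the MEF ratio had a Pearson correlation of 0.40 with the Tet1CD change of the Vc- table and of 0.53 with that of the Vc+ table.

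A further control library, listed with the MEFs, is titled 5C without the word MEF, and its column is headed X5CDay4. The labels explain neither the term nor the day, so it may differ from the MEF control in time or treatment. The 5C library stood apart from the MEF control (Spearman correlation across genes 0.67, against 0.95 to 0.99 for the other MEF libraries), with 1987 genes at least 2-fold higher and 2721 lower. The matrix protease Mmp3 went from 39 to 10854, complement C1qa from 1 to 486, Apoe from 38 to 2500 and Agtr2 from 119 to 6727, while the contractile gene Cnn1 went from 1708 to 12 and Masp1 from 729 to a listing at 0. Interferon-stimulated genes were at least 2-fold higher in 22 of 25 cases (median 3.12) and the 6 macrophage markers in all cases, with Laptm5 at 439. G2/M genes were at least 2-fold lower in 24 of 30 cases and G1/S genes in 17 of 34, such as Rrm2 (1167 to 37) and Plk1 (385 to 14). Dnmt1 was 100 against 957.

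Vitamin C itself could be read only across tables that had been normalized separately, so no test was made, and each gene's ratio was taken relative to the median gene of its pair (0.52 to 0.57 on the log2 scale). Interferon-stimulated genes were higher with vitamin C in all 7 pairs of matched constructs for 17 of 20 measured genes, 11 of them with a median of at least 2-fold. Oas2 had a median log2 ratio of 2.55 (SD 0.63 over 7 pairs), Oasl2 of 1.60 (SD 0.78), Xaf1 of 1.59 (SD 0.35), Rtp4 of 1.55 (SD 0.96) and Bst2, the antiviral tetherin, of 1.41. Spn and Ecel1 (1.73 each), Dmrtc2 and Cml3 (1.66 each), Fetub (1.58) and the epithelial keratin Krt8 (1.38, SD 0.37) were also higher. The genes named at the other end were Lox (-1.45, SD 0.67), Hey2 (-1.32, SD 0.31), Flrt2 (-1.28), Sema3c (-1.28), Cdh11 (-1.24), Flt1 (-1.14), Cdo1 (-1.38) and Cacna1g (-1.41). Of 36 mesenchymal genes 8 were lower in all pairs. In all, 42 genes were higher and 23 lower in all 7 pairs with a median of at least 2-fold, and 23 higher with a pseudocount of 20. The direction was the same in all pairs for 14.9% of 10711 genes, where independent pairs would give 1.56% by chance, although pairs that share a normalization are not independent. With a pair left out, 64 genes were higher without the control pair or the pair labelled Dnmt1, 66 without the shDnmt1 pair and 67 without the pair with shp53 and shDnmt1.

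SKOM cells differed from MEFs in factors, medium and days at once, and the tables were again normalized separately, so ratios were taken relative to each pair's median (-0.30 to -0.27 without vitamin C and 0.24 to 0.31 with it). Fibroblast genes were lower and several epithelial genes higher in SKOM cells. The chemokine gene Cxcl12 had a median log2 ratio of -5.27 without and -5.36 with vitamin C, the matrix proteoglycan Bgn of -4.22 and -4.60, Smoc2 of -4.13 and -4.48, Dlk1 of -4.04 and -4.24, Fbln2 of -3.61 and -3.84 and periostin (Postn) of -3.47 and -3.62. In the mesenchymal list 23 of 36 and 27 of 37 genes were lower in all 5 pairs with a median of at least 2-fold, and 1 gene in each medium was higher by the same measure. The integrin gene Itgb4, part of epithelial hemidesmosomes, stood at 6.75 and 7.12, the actin nucleator Cobl at 5.58 and 5.02, Prelp at 4.56 and 4.32 and Dsp at 3.61 and 4.05. By that measure 4 and 3 of 5 measured epithelial genes were higher, with 1 lower with vitamin C. Imprinted genes were lower in 10 and 11 of 33 cases and higher in 1, among them Igf2 (-2.79 and -3.62) and H19 (-2.85 and -3.19). Immediate early genes were lower in 3 of 12 and 8 of 13 cases, with Fos at -2.34 and -1.99. The DNA methyltransferase gene Dnmt3a (1.26 and 1.27) was higher, as were the retrovirally supplied Myc (4.66 and 3.54) and Klf4 (3.58 and 3.79). Dnmt1 had medians of 1.11 and 0.99 over pairs that include the hairpin and Tet1CD, with which it was also lower in MEFs, and in the control pair it was 984 without and 2346 with vitamin C against 957. In all, 617 genes were higher and 764 lower without vitamin C and 724 and 1163 with it, each in all 5 pairs with a median of at least 2-fold. The direction was the same in all 5 pairs for 62.5% and 63.1% of genes, against 6.25% by chance for independent pairs.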

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

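The tests of the repeat element, of genes of the same level, of Atp5f1 with Erp29 and of macrophage RNA were chosen after the results they bear on had been seen, as was the way of counting splits for Vc by Tet1CD; the other split tests and the rank test were fixed earlier.

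The response to Tet1CD differed between media by the interaction test for 918 genes upward and 887 downward. With predicted genes and genes without a symbol left out, the largest in each direction were Wdr31 (6.02), Rab3gap1 (4.66), D7Ertd715e (4.56), Slc38a6 (4.06), Baiap2l1 (3.77), Cep112os2 (3.46), Tslp (3.28) and Kif24 (3.25), and Arhgap36 (-3.01), Slc16a3 (-2.96), Fut9 (-2.92), Cdh7 (-2.63), Frem2 (-2.30), Bex4 (-2.18), Celsr1 (-2.09) and Alpl (-2.09). The values of Fut9 and Cdh7 are fitted values that include listings at 0. Of the genes left out, ENSMUSG00000102712 (4.66) and Gm29084 (4.45) lay above Slc38a6. Of the 98 distinct models, 5 called as many genes as the real 1805, the highest other 5441, so chance is not excluded for this count; 3 ways of counting gave 5 of 100, 5 of 100 and 5 of 98. The split with 5441 kept the 3 Tet1CD labels of the Vc+ table and gave those of the Vc- table to 3 libraries without Tet1CD, so by construction its contrast adds the Tet1CD effects of both tables, a structure of the samples. The effect of shp53 differed between media for 4 genes: Fap (-4.71) and Gabra3 (-3.43), both listed at 0 in the Vc+ library with shp53, and Ddx5 (-1.55) and Hnrnpu (-1.27), which stand at the highest value of their table in several libraries.

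The first pattern weighed is the 241 genes whose Tet1CD response was at least 2-fold higher with vitamin C. Reads from a repeat element found in Slc38a6 and Rab3gap1 may explain a few, several of the largest differences among them. Besides those genes, 39 measured genes carry a copy. Of these, 8 are among the 241, against a mean of 0.966 and a highest of 6 in 10000 matched gene sets, and the other carriers are not. Wdr31 (6.02), ENSMUSG00000102712 (4.66), Gm29084 (4.45), Cep112os2 (3.46) and Kif24 (3.25) are among these 8. For the rest this explanation is argued against, since 231 carry no copy in an annotated transcript, Baiap2l1 and Tslp included. The authors' normalization stays open as a part of it: 99.2% of the 241 ranked higher in each of the 3 Vc+ Tet1CD libraries than in each of the other 4, but ranks restate values in libraries that share a list of values, and the 100 genes nearest in level, which a normalization that keeps the order of genes moves alike, had a median interaction under 0.25 of the gene's own for only 54.8% of the 241, short of the 90% set for excluding it (median 0.30 against 1.23, highest 0.74). The median of those nearest genes reached at least 0.5 of the gene's own for only 3.73% of the 241. The lowest difference among the 241 was 1.00, so these medians stayed below each of them. A dependence of the Tet1CD response on vitamin C, a cofactor of Tet enzymes, also stays open as a hypothesis, as does chance for the count.

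The second pattern is the fall of Atp5f1 and Erp29 with the Dnmt1 hairpin. Lower Dnmt1 as the cause was examined in the 3 pairs where Tet1CD lowered Dnmt1 without the hairpin (mean log2 ratio -1.04). There Erp29 had a mean of 0.019 (SD 0.142). It had -0.68 in the 4 SKOM hairpin pairs, where Dnmt1 had a mean of -0.94. Erp29 thus passed the bound set against lower Dnmt1. The 3 pairs also differ by Tet1CD, whose own effect on Erp29 could hide a fall, so lower Dnmt1 is not excluded for it. For Atp5f1 lower Dnmt1 stays open, since its mean of -0.21 (SD 0.343) includes a pair at -0.59, near the highest of those hairpin pairs (-0.67, mean -0.97); an earlier form of this test, against all 6 hairpin pairs (mean -1.32, SD 0.632, with Dnmt1 at -1.32), had argued against it for both genes and was narrowed after these values had been seen, because Dnmt1 fell further in the MEF pairs. A direct action of the hairpin or its vector needs both genes to fall in the 2 MEF hairpin pairs, which had no part in their choice. The highest ratio of either gene there was -0.93. Dnmt1 itself had -2.18 and -1.97 in these pairs, so lower Dnmt1 predicts such falls too, and the pairs cannot tell these explanations apart. An off-target action may be a candidate explanation that these values do not single out. Hairpin sequences were not analysed here, and no biological explanation beyond lower Dnmt1 was tested.

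The third pattern is the rise of macrophage markers with Tet1CD in SKOM cells. In Vc+ cells, macrophages in the cultures are argued against by a single abundant macrophage transcript, Lyz2: its ratio to Laptm5 was at most 0.0246 in the 3 Vc+ Tet1CD libraries (Lyz2 29 to 53, Laptm5 1578 to 2156) and 6.75 to 11.3 in the 4 MEF libraries with macrophage transcripts. In Vc- cells they stay open, since Lyz2 is not listed there and the ratio of Cd68 to Laptm5, at most 0.169 in the 3 Vc- Tet1CD libraries against 1.42 to 2.20 in those MEF libraries, was lower but did not pass the bound used for Lyz2 in every library. An activation of Laptm5, Ptprc and Cd68 in the reprogramming cells themselves may be a hypothesis that these values leave open.

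For the counts of the additive model except shp53, for Vc by shDnmt1 and for Tet1CD in each table, other splits of the libraries gave the following. Chance is argued against for Tet1CD (1 of 100 splits, the real one included, real 4842, highest other 2147). The share was also under 0.05 for shDnmt1 (2 of 100, real 2, highest other 1641) and for the libraries labelled Dnmt1 against shDnmt1 (1 of 100, real 2, highest other 1). Those counts of 2 genes fell to 0 without single libraries, so chance is not excluded for the counts themselves. For the fall of Atp5f1 and Erp29 with the hairpin, the 2 MEF hairpin pairs, which had no part in their choice, argue against chance. The log2 ratios there were -2.40 and -1.65 for Atp5f1 and -1.40 and -0.93 for Erp29. The SD of the ratios of all genes with a mean of at least 50 was 0.287 and 0.344 in these pairs. The split with 1641 genes followed Tet1CD in opposite ways in both tables, so it points to that structure. For the libraries labelled Dnmt1 (100 of 100, real 0, highest other 23) and Vc by shDnmt1 (100 of 100, real 0, highest other 72) every split calls at least the real 0, so chance is not excluded and the splits say no more than that. For Tet1CD in the Vc- table (real 1568, highest other 0) and the Vc+ table (real 5319, highest other 0) the 7 splits are too few for a share under 0.05.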

How the results depend on the processing

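The alternatives for the interactions and single tables and the Vc by Tet1CD term were chosen after the results had been seen; the others were planned. Counts stayed within 1.5 times under 450 combinations of count and alternative and moved further under 118; named genes kept direction and side of the threshold in 1275 (98 of them for the 4 genes of the Dnmt1 effect, which had no call), lost the call in 157 and turned in 1 (Wdr31 with Tet1CD, -0.19 in the Vc- table alone). No paired analysis was possible because of the replicate numbers, which are 1 throughout and pair no libraries; libraries matched by their other constructs were fitted as blocks instead. The cause of these moves was not tested, except where fewer genes or libraries enter by construction. Depth is unknown, so what it limits cannot be stated.

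With the MEF libraries added, shDnmt1 gave 3 genes higher and 14 lower, Dnmt1 against shDnmt1 5 and 1, and shp53 1217 and 1188. With a Vc by Tet1CD term, shDnmt1 gave 1 and 5, Dnmt1 against shDnmt1 5 higher, and shp53 109 and 344. The Vc- table alone gave 777 and 791 for Tet1CD, 4 and 9 for shp53 and 0 lower for shDnmt1; the Vc+ table alone gave 0 for shDnmt1 lower, 0 for Dnmt1 against shDnmt1 higher and 2 lower for shp53. At 2-fold or more, counts were 163 and 73 for Tet1CD, 45 and 14 in the Vc- table, 739 and 484 in the Vc+ table, 241 and 133 for Vc by Tet1CD, and 0 for shDnmt1 lower and Dnmt1 against shDnmt1 higher. Without the trend, they were 204 and 100 for Tet1CD in the Vc- table, 2 lower for Vc by shp53 and 1 higher for shp53. TMM-type scaling gave 3 lower for shp53 and 1 lower for Vc by shp53, quantile normalization 2 lower for Vc by shp53, a mean of at least 50 2 lower for shp53, pseudocount 1 3 higher for Vc by shp53, and the 4 pairs as a block 1 lower for Dnmt1 against shDnmt1. Pseudocount 20 gave 23 higher for the Vc effect and, in MEFs at 2-fold, 12 lower for Dnmt1, 19 and 19 for shDnmt1 and 96 lower for Tet1CD. With an estimated correlation 0 lists passed for Dnmt1, Dnmt1 against shDnmt1, Tet1CD, shp53, Vc by Tet1CD and Tet1CD in either table, and fry gave 0 for Dnmt1, Dnmt1 against shDnmt1 and shp53.

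With 1 library left out at a time, counts ranged as follows. Tet1CD had 1690 to 2390 higher and 2011 to 2925 lower, with 3 to 1158 and 2 to 1202 in the Vc- table and 1146 to 2537 and 1049 to 2943 in the Vc+ table. Vc by Tet1CD had 450 to 1148 higher and 311 to 1173 lower, Vc by shp53 0 to 17 and 0 to 11. For shDnmt1 0 to 1 were higher and 0 to 3 lower, for Dnmt1 against shDnmt1 0 to 3 higher, and for shp53 1 to 5 lower. The Vc effect had 36 to 67 genes higher. Vc by Tet1CD and Vc by shp53 without either shp53 library could not be fitted. The planned tests between tables and their limma alternatives were not run.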

Other observations

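Gene groups outside the account above also moved with Tet1CD in Vc+ cells. Of 30 hypoxia-response and glycolysis genes 17 fell and 3 rose (19 and 4 adjusted over the list alone; median -0.43; adjusted p = 0.373 with an estimated correlation): the lactate exporter Slc16a3 (-2.84 ± 0.19), the aldolase Aldoc (-1.92), Bnip3 (-1.85) and the kinase Pdk1 (-1.49) fell, while the endoplasmic reticulum oxidase Ero1l rose by 1.26. The interaction with vitamin C was negative for 11 of 28 such genes and positive for 1 (13 and 1 adjusted over the list alone; adjusted p = 0.0991 with an estimated correlation), with Bnip3 at -1.97 ± 0.14. Of 23 cholesterol synthesis genes 10 fell (13 fell and 2 rose adjusted over the list alone; adjusted p = 0.338 with an estimated correlation), and the interaction was negative for 6 of 22 (10 adjusted over the list alone; adjusted p = 0.0991 with an estimated correlation), with Mvd at -0.79 and Hmgcs1 at -0.55. The 3 measured skeletal muscle markers rose (3 adjusted over the list alone; adjusted p = 0.338 with an estimated correlation): Des by 2.43 ± 0.12, Chrna1 by 1.35 and Acta1 by 0.81.

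In the additive model over both media, imprinted genes went both ways with Tet1CD, 8 of 33 rising and 10 falling (9 and 10 adjusted over the list alone), with Mest at -0.96 ± 0.16, the growth inhibitor Cdkn1c at -0.85 and Peg12 at -0.79. Of 21 measured Hox genes 7 rose and 1 fell (7 and 1 adjusted over the list alone), Hoxb8 by 0.55 ± 0.17 and Hoxc10 by 0.50 upward. Of 18 stress response genes 7 rose and 7 fell (7 and 7 adjusted over the list alone), with Nupr1 at 0.99 ± 0.10 and the stress transcription factor Ddit3 (CHOP) at 0.97 ± 0.14. In the list of DNA methylation and demethylation genes 3 of 18 rose and 10 fell (3 and 10 adjusted over the list alone); the methyl-CpG binding zinc finger gene Zbtb38 rose by 1.21 ± 0.10, whereas Uhrf1 (-0.83 ± 0.15), the partner of Dnmt1 at replication forks, and Tet2 (-0.79 ± 0.20) fell. None of these 4 lists was called by camera in that model.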
